A study of Homo sapiens with 34 samples.

How the data were processed

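The deposited file holds a whole-series matrix of expected counts per gene for 34 libraries, made by the authors before deposition; the file's name points to salmon, a tool that assigns reads to transcripts and sums them to genes. The submitters' processing notes instead list FastQC 0.12.1, Trim Galore 0.6.10, MultiQC 1.30, STAR 2.7.11b, featureCounts 2.0.6, R 4.5.1 and DESeq2 1.48.2 with the build GRCh38.p14, give these tools no roles and do not list salmon. Of the nonzero values 28.7% are not whole numbers, as estimated counts are and as plain featureCounts output is not. The release of the gene annotation is not given in the sources used here. Counts were rounded to whole numbers before testing. They come from amplified libraries without molecular tags, so amplification copies are counted as reads.

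According to the labels, total RNA was taken from muscle with a lysis reagent and column purification, the libraries were directional poly(A) libraries and sequencing was on an Illumina NovaSeq. Each library is 1 biopsy of 1 person, so replicates are separate people. The labels' batch field holds the words Before and After, so a processing batch that followed time could not be told apart from training. The file held 62754 genes in 34 columns, all matched to a library. Library totals had a median of 44.46 M counts, with group means of 43.7 ± 3.12 M (BFRT Before), 44.3 ± 5.02 (BFRT After), 45.5 ± 2.96 (CREST Before) and 45.1 ± 2.84 (CREST After). Between 22650 and 26380 genes had counts above 0.

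XIST, TSIX and genes of the Y chromosome, 595 in all, were removed before testing, which left 62159. Antigen receptor, immunoglobulin and HLA genes were tested and are not named, because they can vary with a person's genotype. A check for mixed-up samples by sex-linked genes found 0 mismatched pairs of libraries. The pairing by participant was checked on log2 CPM centred gene by gene within each group. The lowest correlation between the Before and After libraries of 1 participant was 0.215 and the median 0.436, against a median of −0.029 between different participants. The After library correlated best with its own Before library in 17 of 17 participants. Between libraries of a group, the smallest mean squared difference was 33.95 times the counting variance, so no library repeats another.

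Groups, comparisons, 44 gene lists and the rule for named genes were fixed before the data were examined. The tests within people used edgeR 4.0.16 with filterByExpr (minimum count 10, minimum total 15), TMM normalization, robust quasi-likelihood fits, 1 block term per participant and 1 After term per arm. From that fit came the change in BFRT, the change in CREST, their difference and their mean, on 17086 genes with 15 residual degrees of freedom and a biological coefficient of variation of 26.3%. The comparison of arms before training used the 17 Before libraries and 16136 genes. P values were adjusted by the Benjamini-Hochberg method over all genes of a comparison at 0.05. Levels are CPM, counts scaled to each library's normalized total, and log2 CPM used a prior count of 2.

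Named genes are the 6 rises and 6 falls with the largest absolute log2 fold change at an adjusted p below 0.05, a mean CPM of at least 1 and the same direction in at least 3 of every 4 participants. Where none passed, the 3 smallest p values per direction are given as values, and for the difference and the comparison before training the 2 smallest. In addition come up to 4 members with the smallest p of each list that passed, 2 of others, and 18 genes chosen beforehand, from PPARGC1A to KDR. PRND and LY6H have a low level and are given as values.

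Gene lists were tested with limma 3.58.1 camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted at 5% over the lists of a comparison. Camera compares a list with all other genes, so its direction can differ from the sign of the list's median. Camera with an estimated correlation and fry were run beside it. A list needed at least 5 members past the count filter, which 43 lists had; the metallothionein list had fewer and was not tested. Lists share members, so they are not independent, and only some shared members are named here. THBS4 and COL1A1 are in the matrix and tendon lists, and SPARC in the matrix and basement membrane lists. TIE1 is in the endothelial and angiogenesis lists, and PDGFRB in the angiogenesis and pericyte lists. COL15A1, DCN, LUM and FBN1 are in the matrix and progenitor lists. AGRN is in the basement membrane and neuromuscular junction lists, NOTCH3 in the pericyte and satellite cell lists and PLIN4 in the adipocyte and lipid droplet lists. No red blood cell gene is in another list. A test per participant on the mean change of a list was added after the result was seen, with exact sign flips within an arm, exact permutation of arms for the difference and 100000 sign-flip resamples for the mean.

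Other settings chosen beforehand were DESeq2 1.42.0, limma voom with a participant correlation (0.267), RLE normalization, no filter, a stricter filter, 1 surrogate variable (sva 3.50.0), no participant block, each arm alone and leaving out each participant. For gene lists the filter settings and the surrogate variable were added later. Other fits were added after the data were seen. These were a fit without the participant whose Before library held 12.3% hemoglobin counts, a fit with hemoglobin as a covariate, and both together. The covariate was the mean log2 CPM of HBA1, HBA2 and HBB. A correction for GC content and length (longest transcript in GENCODE v29, known for 96.4% of tested genes) was added too, with and without that participant. In a simulation built on these libraries 53% of 1.5-fold and 91% of 2-fold changes in BFRT were recovered, with 3 false calls. Simulated changes were placed outside low-count genes, and no blood-rich pair was simulated, so recovery in the real data may be lower. R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. Reads were not analysed here, and neither were isoforms, splicing or variants.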

Results

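The libraries come from the vastus lateralis, a thigh muscle, of people with type 2 diabetes who trained for 12 weeks. The series title names mitochondrial oxidative capacity and cardiovascular risk factors as its subject. Blood flow restriction training (BFRT) was done by 9 people and classical resistance training (CREST) by 8. Each person gave 1 biopsy 24 h before the training period and 1 biopsy 72 h after it, which makes 34 poly(A) libraries in 4 groups. Library totals ran from 36.97 to 54.1 M counts, and 17086 genes had enough counts to be tested for a change within people.

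Hemoglobin transcripts, which come from red blood cells, made up 1.499 ± 4.05% of counts Before and 0.108 ± 0.142% After in BFRT (mean ± SD, n = 9, exact sign-flip p = 0.0195), and fell in 8 of the 9 people. In CREST the hemoglobin share went from 0.310 ± 0.267% to 0.124 ± 0.111% (n = 8, exact p = 0.00781) and fell in 8 of 8. The high mean and wide spread in BFRT Before come from 1 library at 12.3% hemoglobin, with the next highest in that group at 0.438%. Without that participant the share went from 0.150 ± 0.133% to 0.0616 ± 0.0351% (n = 8, exact p = 0.0391). Transcripts of the mitochondrial genome rose from 19.2 ± 2.66% to 22.6 ± 2.65% of counts in BFRT (n = 9, exact p = 0.00391), in 9 of 9 people. In CREST they went from 19.1 ± 2.56% to 20.9 ± 4.33% (n = 8, exact p = 0.0859).

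After BFRT, genes that passed and rose included 15 of 34 extracellular matrix genes and 11 of 22 endothelial genes, and genes that fell included 3 of 7 red blood cell genes. As lists these had adjusted p = 0.133, 0.107 and 0.181 with an estimated correlation. With fry the adjusted p values were 0.00715, 0.00253 and 0.0233. Over participants they were 0.0336, 0.0336 and 0.0784, in a test added after the result was seen. The matrix proteoglycan gene BGN rose by 1.39 log2 (SE 0.22, n = 9, adjusted p = 0.00513), and THBS4, a thrombospondin of the matrix, rose 2.79-fold (log2 SE 0.21, n = 9, adjusted p = 0.00373). COL4A1, which encodes a basement membrane collagen, went from 53.7 ± 9.32 to 148 ± 34.5 CPM (counts scaled to the library total) and rose in 9 of 9 people. Matrix, basement membrane and endothelial genes are known to be active when muscle capillaries and connective tissue are remodelled. Neither arm was left untrained, so a change from Before to After holds whatever else differed between the biopsies, the blood they held included.

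In BFRT 413 genes passed at an adjusted p below 0.05, of which 332 rose and 81 fell, and 2967 genes had an unadjusted p below 0.05. Among the 332 rises the median fold was 1.59 (0.67 log2), and 53 rises and 15 falls were larger than 2-fold. The median fall was −0.32 log2. Without the participant whose Before biopsy was rich in blood, 1595 genes passed (907 higher and 688 lower), and 410 of the 413 were still among them. Other settings lowered the count: to 0 with hemoglobin (mean log2 CPM) as a covariate (edgeR, 1358 at an unadjusted p below 0.05), to 42 with that arm fitted alone and to 109 without 1 other BFRT participant. The largest rises were those of THY1 (1.73 log2, SE 0.35), IGFN1 (1.70, SE 0.39), THBS4, MXRA5 (1.47, SE 0.28), COL4A1 (1.44, SE 0.22) and BGN. THY1 is a surface marker of fibroblast-like and vessel-wall cells, IGFN1 a muscle Z-disc protein gene and MXRA5 a secreted matrix protein gene. THY1 went from 2.14 ± 1.26 to 7.17 ± 3.71 CPM and THBS4 from 35.4 ± 13.6 to 91.1 ± 24.0, each in 9 of 9 people. IGFN1 went from 96.1 ± 113 to 258 ± 291 CPM, in 8 of 9.

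The largest falls in BFRT were those of MGAM (−2.60 log2, SE 0.59, adjusted p = 0.0268), FFAR2 (−2.36, SE 0.54), APOBEC3A (−2.30, SE 0.52), FCGR3B (−2.30, SE 0.54), FPR1 (−2.29, SE 0.58) and ADGRG3 (−2.27, SE 0.51). FFAR2, FCGR3B, FPR1 and ADGRG3 are known neutrophil genes, and MGAM and APOBEC3A are also high in blood leukocytes. Over 17 people the change in 5 further neutrophil genes (CXCR2, CSF3R, S100A8, S100A9 and S100A12) correlated with the change in the hemoglobin share (r = 0.902, rho = 0.831). Without the blood-rich participant MGAM stood at −1.91 log2 (SE 0.51) and FFAR2 at −1.76. FCGR3B and APOBEC3A have near-identical paralogs, so their counts are less certain.

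In the files THY1 is ENSG00000154096.14 (chromosome 11, 119415476 to 119424985), IGFN1 is ENSG00000163395.17 (chromosome 1, 201190824 to 201228952) and THBS4 is ENSG00000113296.14 (chromosome 5, 79991332 to 80083287). MXRA5 is ENSG00000101825.8 (chromosome X, 3308565 to 3346652), COL4A1 is ENSG00000187498.16 (chromosome 13, 110148963 to 110307157) and BGN is ENSG00000182492.16 (chromosome X, 153494980 to 153509546). COL3A1 is ENSG00000168542.17 (chromosome 2, 188974373 to 189012746), MGAM is ENSG00000257335.8 (chromosome 7, 141986518 to 142106747), FFAR2 is ENSG00000126262.5 (chromosome 19, 35448257 to 35451767) and MYH1 is ENSG00000109061.10 (chromosome 17, 10492307 to 10518542). Coordinates are those of GRCh38.p14.

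The extracellular matrix list moved up in BFRT: 15 of 34 members rose over all genes, 21 with p values adjusted over the list alone, and 32 were positive. Its median change was 0.53 log2 (1.45-fold), with an adjusted p = 0.133 with an estimated correlation and an exact sign-flip p = 0.00391 over participants. COL3A1 rose from 49.5 ± 23.8 to 126 ± 52.0 CPM (1.36 log2, SE 0.22, adjusted p = 0.00546), LOXL2 by 1.15 (SE 0.21) and COL1A1 by 1.18 (SE 0.29). The mean change over the list was 0.59 log2 (SD 0.41, n = 9), above 0 in 9 of 9 people. Its median was 0.51 log2, with 19 members rising, when the blood-rich participant was left out.

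Basement membrane genes had a median of 0.63 log2 in BFRT, with 8 of 17 members rising over all genes, 12 over the list alone and 17 positive (adjusted p = 0.107 with an estimated correlation). LAMB1 rose by 1.003 log2 (SE 0.15, adjusted p = 0.00513), COL4A2 by 1.31 (SE 0.21) and AGRN by 0.80 (SE 0.14). Endothelial genes had a median of 0.51 log2, with 11 of 22 rising over all genes, 20 over the list alone and 22 positive (adjusted p = 0.107 with an estimated correlation). ERG rose by 0.75 log2 (SE 0.11, adjusted p = 0.00373), CLDN5 by 0.73 (SE 0.11), CDH5 by 0.69 (SE 0.13) and CLEC14A by 0.65 (SE 0.13). Angiogenesis genes had a median of 0.46 log2, with 10 of 32 rising over all genes and 19 over the list alone (adjusted p = 0.133 with an estimated correlation). APLNR rose by 0.89 log2 (SE 0.14), NRP2 by 0.93 (SE 0.19) and KDR by 0.65 (SE 0.17), while VEGFA stood at 0.58 (SE 0.23, adjusted p = 0.202). Pericyte and smooth muscle genes had a median of 0.57 log2, with 4 of 17 rising over all genes and 8 over the list alone (adjusted p = 0.133 with an estimated correlation). KCNJ8 rose by 1.07 log2 (SE 0.15, adjusted p = 0.00368) and ACTA2 by 0.95 (SE 0.22). With fry the basement membrane, endothelial, angiogenesis and pericyte lists had adjusted p = 0.00253, 0.00253, 0.00699 and 0.00715. Over participants, in the test added later, they had 0.0336, 0.0336, 0.0373 and 0.0336 adjusted.

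Respiratory chain genes had positive medians in BFRT, with few members passing. The list of complexes II to V had a median of 0.38 log2 (1.303-fold), with 2 of 41 members rising over all genes, 15 over the list alone and 41 positive (adjusted p = 0.487 with an estimated correlation, exact sign-flip p = 0.00781). COX7A2 rose by 0.39 log2 (SE 0.07, n = 9, adjusted p = 0.00718) and UQCRH by 0.47 (SE 0.12, adjusted p = 0.0414), and COX4I1 stood at 0.43 (adjusted p = 0.0634). Complex I had a median of 0.32 log2, with 37 of 37 members positive and 1, NDUFB1, rising over all genes (adjusted p = 0.531 with an estimated correlation). Genes encoded by mitochondrial DNA had a median of 0.30 log2, with 13 of 13 positive and 0 passing over all genes (adjusted p = 0.487 with an estimated correlation). MT-CO2 stood at 0.44 log2 (SE 0.15, adjusted p = 0.132). The medians fell to 0.18 log2 for complexes II to V, 0.12 for complex I and 0.17 for mitochondrial DNA without the blood-rich participant, and 17, 9 and 3 members rose.

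Fatty acid oxidation genes had a median of 0.28 log2 in BFRT with 1 of 24, DECR1, rising over all genes (0.43, SE 0.09, adjusted p = 0.0219), and the list had adjusted p = 0.531 with an estimated correlation. Tricarboxylic acid cycle genes had a median of 0.27 log2 with 19 of 19 positive and 0 passing (adjusted p = 0.610 with an estimated correlation), PDHB standing at 0.41. Mitochondrial ribosome genes had a median of 0.21 log2 with 28 of 32 positive and 0 passing (adjusted p = 0.699 with an estimated correlation), MRPS5 standing at 0.24. Leaving out the blood-rich participant took the medians to 0.0992 log2 for fatty acid oxidation, 0.0458 for the tricarboxylic acid cycle with 15 of 19 positive, and 0.0374 for the mitochondrial ribosome. Glycolysis genes had a median of 0.22 log2 (adjusted p = 0.723 with an estimated correlation) and slow fibre genes one of 0.21 (adjusted p = 0.724 with an estimated correlation), with 0 members passing in either. LDHB stood at 0.27 log2 and HSPB6 at 0.52. Glycolysis and slow fibre medians were −0.02 and −0.08 log2 without the blood-rich participant. In that participant the change was 1.95 log2 over glycolysis genes and 3.58 over slow fibre genes, the next highest in the arm being 0.07 and 0.77.

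Red blood cell genes had a median of −1.46 log2 in BFRT, with 3 of 7 members falling over all genes and 6 over the list alone (adjusted p = 0.181 with an estimated correlation). ALAS2 fell by 2.03 log2 (SE 0.44, adjusted p = 0.0213), SLC4A1 by 1.79 (SE 0.42) and HBM by 2.29 (SE 0.57). Lymphocyte genes (T, NK and B cells) had a median of −0.78 log2 with 0 of 23 positive and 0 passing over all genes (adjusted p = 0.610 with an estimated correlation), IL7R standing at −1.41. Their median was −0.26 log2, with 3 of 8 people rising, when the blood-rich participant was left out. Inflammatory genes had a median of −0.15 log2 with 2 members falling, IL1RN (−2.65, SE 0.64) and IL32 (−1.02, SE 0.20), and adjusted p = 0.648 with an estimated correlation, and a median of 0.0611 log2 with 9 of 15 positive without the blood-rich participant. The hemoglobin share fell in 8 of the same 9 people.

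Ribosome biogenesis genes had a median of −0.11 log2 in BFRT with 1 of 32, NOP58 (−0.27, SE 0.06, adjusted p = 0.0224), falling over all genes, 4 over the list alone and 6 positive (adjusted p = 0.202 with an estimated correlation). Cytosolic ribosomal protein genes had a median of −0.07 log2 with 0 passing (adjusted p = 0.723 with an estimated correlation), RPS27 standing at −0.20. Tendon and fascia genes had a median of 0.12 log2 with 4 of 10 rising, THBS4 and COL1A1 among them (adjusted p = 0.191 with an estimated correlation). Satellite cell genes had a median of 0.16 log2 with 3 of 20 rising, and these are the Notch pathway genes HEYL (0.79, SE 0.14), HEY1 (0.73) and NOTCH3 (0.57), which vessel cells also express (adjusted p = 0.610 with an estimated correlation). The satellite cell median was −0.03 log2, with 8 of 20 positive, when the blood-rich participant was left out. Matrix protease genes had a median of 0.25 log2 over 21 members (adjusted p = 0.531 with an estimated correlation). Fibro-adipogenic progenitor genes had a median of 0.13 log2 with 4 of 21 rising, COL15A1 (0.77) and CD34 (0.60) among them (adjusted p = 0.721 with an estimated correlation). Myokine genes had a median of 0.25 log2 with 0 of 19 rising over all genes and 2 over the list alone (adjusted p = 0.495 with an estimated correlation). Antioxidant genes had a median of 0.11 log2 with 1 of 24, NQO1 (0.68), rising (adjusted p = 0.495 with an estimated correlation).

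The other lists did not pass camera in BFRT. Schwann cell genes had a median of 0.27 log2 and an adjusted p = 0.0604, immediate early genes −0.20 (adjusted p = 0.0604) and macrophage genes −0.19 (adjusted p = 0.0604). Macrophage genes changed by −3.45 log2 in the blood-rich participant, the next lowest being −0.87, and rose in 5 of 9 people. Proliferation genes had a median of 0.09 log2 and a mean of 0.41, with MKI67 at 2.09 and TOP2A at 1.76. Medians were 0.15 log2 for neuromuscular junction genes, 0.12 for mitochondrial biogenesis, 0.07 for interferon response (IFI27 rose by 0.79), 0.05 for hypoxia response, 0.10 for complement and 0.01 for muscle growth signalling. In the last of these IGF2 rose by 0.98 log2 (SE 0.17) and FOXO1 fell by 0.41 (SE 0.10). Adipocyte genes had a median of −0.09 log2, lipid droplet genes 0.03, calcium handling −0.02, heat shock 0.02, fast fibre 0.02, clock 0.03, developmental muscle genes −0.00, insulin signalling 0.01 and proteasome −0.00. Leaving out the blood-rich participant took heat shock genes to −0.17 log2, clock genes to −0.17, developmental muscle genes to −0.19, calcium handling to −0.23 and fast fibre genes to −0.25, and these lists then passed at the preset correlation. Interferon genes (0.31 log2), proteasome genes (−0.09) and muscle growth genes (−0.08) passed in that fit too. For lipid droplet, fast fibre and clock genes the median and the mean or the test differ in sign, and for heat shock, insulin signalling and proteasome genes the mean and the test do.

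The single genes named beforehand for metabolism, fibre type and muscle mass did not pass in BFRT. PPARGC1A stood at 0.54 log2 (SE 0.24, adjusted p = 0.260), CS at 0.27 (SE 0.18, adjusted p = 0.463), CD36 at 0.29 (SE 0.12), SLC2A4 at 0.25, HK2 at −0.35 and PDK4 at 0.37. MYH1 stood at −1.51 log2 (SE 0.63), MYH2 at 0.48, MYH7 at 0.19, MSTN at −0.73 (SE 0.33, adjusted p = 0.266), FBXO32 at 0.34, TRIM63 at 0.21 and PECAM1 at 0.47. In the blood-rich participant PPARGC1A changed by 3.27 log2 and CS by 2.28, the next highest being 0.72 and 0.22. Without that participant PPARGC1A stood at 0.27 log2 and CS at 0.05, while MSTN (−0.98, SE 0.28) fell and PECAM1 (0.67, SE 0.15) rose.

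**Figure D1:**
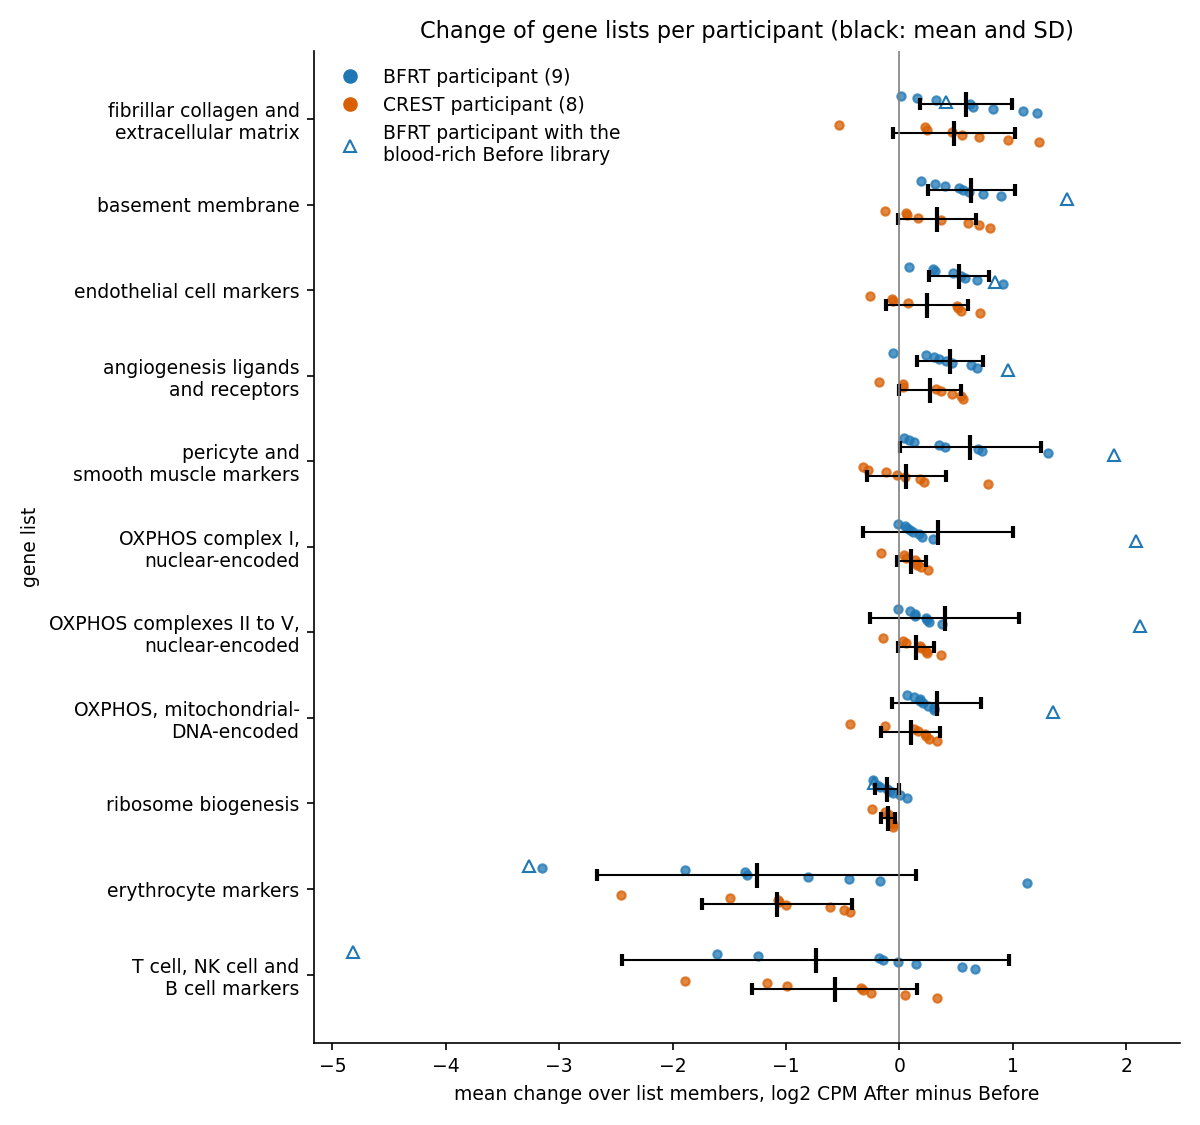
Mean change over the members of each gene list in each participant, in log2 CPM After minus Before, for BFRT (blue, n = 9) and CREST (orange, n = 8). Black marks give the mean and SD of each arm, and triangles mark the BFRT participant whose Before biopsy was rich in blood.

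After CREST 0 genes passed over all genes with edgeR, and the matrix list (median 0.48 log2) and the red blood cell list (−1.22) passed at the preset correlation alone. Each had adjusted p = 0.0782 with an estimated correlation, and over participants they had 0.252 and 0.168 adjusted. COL3A1 stood at 0.91 log2 (SE 0.23, n = 8, adjusted p = 0.468) and THBS4 at 0.87 (SE 0.22, n = 8, adjusted p = 0.468). COL1A1 stood at 0.95 and COL4A1 went from 64.2 ± 20.7 to 120 ± 71.0 CPM (0.73 log2, SE 0.23, n = 8). Resistance exercise is known to raise collagen gene expression in muscle. The smallest adjusted p was 0.109, and 882 genes had an unadjusted p below 0.05 with edgeR (5% of the tested genes is 854.3). That number rose to 2263 without the blood-rich BFRT participant and to 2266 with CREST fitted alone. DESeq2 called 32 genes (26 higher and 6 lower) and voom called 0.

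The smallest p values among positive changes in CREST included those of PRND (adjusted p = 0.109) and LY6H (adjusted p = 0.276). PRND, a prion-like gene active in new vessels, is at chromosome 20, 4721909 to 4728460 (ENSG00000171864.5), and went from 0.0103 ± 0.0217 to 0.364 ± 0.425 CPM. It rose in BFRT too (adjusted p = 0.00127), from 0.0164 ± 0.0362 to 0.586 ± 0.389 CPM, and these levels are too near 0 for a fold. Among negative changes they were SLC4A1 (−1.87, SE 0.43), PSPC1 (−0.24, SE 0.05) and AMOTL2 (−0.51, SE 0.12), each at an adjusted p of 0.436. SLC4A1 is a red blood cell gene, and hemoglobin fell in 8 of the 8 people.

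The extracellular matrix list had a median of 0.48 log2 (1.39-fold) in CREST, with 33 of 34 members positive, 19 passing over the list alone and 0 over all genes (adjusted p = 0.0782 with an estimated correlation). LUM stood at 0.81 log2 (SE 0.18) and COL5A1 at 0.59 (SE 0.14). Over participants the list changed by 0.48 log2 (SD 0.54, n = 8, exact sign-flip p = 0.0469, 0.252 adjusted over lists), above 0 in 7 of 8, and no list passed over participants in CREST. With 8 people exact sign flips can give no p below 0.00781, so several of the 43 lists must lie near that floor before any passes. With 9 people, as in BFRT, the floor is 0.00391. Fibro-adipogenic progenitor genes had a median of 0.41 log2 (adjusted p = 0.189 with an estimated correlation), with PI16 at 0.75, and tendon genes 0.41 (adjusted p = 0.0782 with an estimated correlation). Basement membrane genes had a median of 0.34 log2 with 8 passing over the list alone, LAMB1 (0.70, SE 0.17) and HSPG2 (0.44) among them (adjusted p = 0.152 with an estimated correlation). Matrix protease genes had a median of 0.20 log2 (adjusted p = 0.354 with an estimated correlation), with MMP2 at 0.63. Angiogenesis genes had a median of 0.24 log2 (adjusted p = 0.240 with an estimated correlation), with NRP2 at 0.88 (SE 0.21). Endothelial genes also had 0.24 (adjusted p = 0.277 with an estimated correlation), with ERG at 0.37 and KDR at 0.34.

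Respiratory chain genes of complexes II to V had a median of 0.15 log2 in CREST with 40 of 41 positive, complex I 0.11 and mitochondrial DNA 0.09, each with an adjusted p = 0.875 with an estimated correlation. With hemoglobin as a covariate these medians were negative, −0.08, −0.12 and −0.03 log2, and with the blood-rich participant left out as well they were positive, 0.0893, 0.0585 and 0.0588. COX7A2 stood at 0.27 log2 (SE 0.07, adjusted p = 0.518). Red blood cell genes had a median of −1.22 log2 with 4 passing over the list alone (adjusted p = 0.0782 with an estimated correlation, exact sign-flip p = 0.00781). Lymphocyte genes had a median of −0.72 log2 (adjusted p = 0.46 with an estimated correlation), and hemoglobin fell in the same people. Ribosome biogenesis genes had a median of −0.11 log2 with 31 of 32 negative, DKC1 standing at −0.16 (adjusted p = 0.117 with an estimated correlation). Adipocyte genes had a median of −0.34 log2 with AQP7 at −0.34, and lipid droplet genes −0.11 with PLIN4 at −0.37 (for each list adjusted p = 0.354 with an estimated correlation). In 1 CREST participant adipocyte genes changed by −3.82 log2, the next lowest being −0.44.

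Cytosolic ribosomal protein genes had a median of −0.04 log2 in CREST, fast fibre genes −0.09, calcium handling −0.11, proteasome −0.05 and heat shock −0.08, each with an adjusted p = 0.875 with an estimated correlation. Myokine genes had a median of 0.23 log2 (adjusted p = 0.354 with an estimated correlation). MYH1 stood at −2.38 log2 (SE 0.75, adjusted p = 0.723), PPARGC1A at 0.12, VEGFA at 0.13, CS at 0.09, CD36 at −0.07, SLC2A4 at 0.01, HK2 at −0.29, PDK4 at −0.55, MYH2 at 0.18, MYH7 at −0.13, MSTN at −0.21, FBXO32 at 0.21, TRIM63 at 0.18 and PECAM1 at 0.38. For macrophage, hypoxia and slow fibre genes the median differs in sign from the mean and the test, and none of these lists passed. With 8 people, 47% of simulated 1.5-fold changes and 90% of 2-fold changes, placed outside low-count genes, were recovered, so smaller changes can go uncounted.

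**Figure D2:**
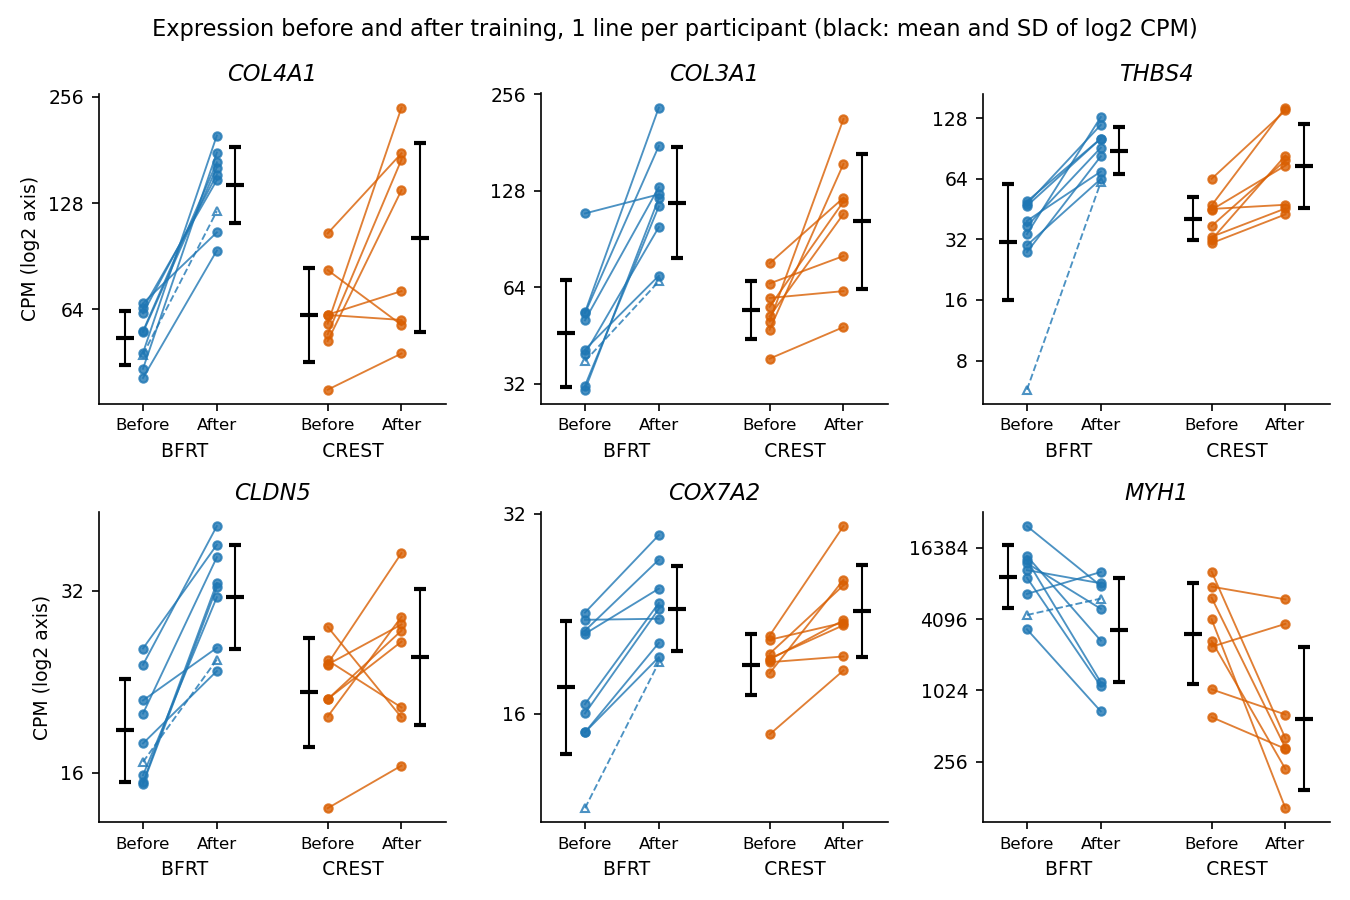
CPM (log2 axis) of COL4A1, COL3A1, THBS4, CLDN5, COX7A2 and MYH1 Before and After in each arm, with 1 line per participant. Black marks give the mean and SD of log2 values, and the dashed line with triangles is the BFRT participant whose Before biopsy was rich in blood.

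Genes that changed in BFRT mostly moved the same way in CREST. Of the 332 genes that rose in BFRT, 316 (95.2%) were positive in CREST, with a median of 0.27 log2 against 0.67. Of the 81 that fell, 78 (96.3%) were negative in CREST, with a median of −0.13 log2 against −0.32. Taken per person, the BFRT rises were above 0 in 6 of 8 CREST participants (exact sign-flip p = 0.0312) and the falls below 0 in 8 of 8 (exact p = 0.00781). In the other direction, 276 of 291 positive genes among the 413 smallest p values of CREST were positive in BFRT, and 112 of 122 negative genes were negative. Their medians were smaller in BFRT than in CREST, 0.46 against 0.55 log2 and −0.21 against −0.28, so in each direction the arm used to choose the genes shows the larger change. Matrix genes such as COL3A1 and THBS4 and neutrophil genes such as FFAR2 are in the shared part.

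The change in BFRT minus the change in CREST passed for 0 genes with edgeR (444 genes at an unadjusted p below 0.05), for 0 with DESeq2 and for 0 with voom. Pericyte and smooth muscle genes had a gap of 0.51 log2 (0.57 in BFRT and 0.07 in CREST), which was 0.36 without the blood-rich participant, less than that of adipocyte genes (0.58) in the same fit. KCNJ8 stood at 0.79 log2 (SE 0.22) and ACTA2 at 1.04 (SE 0.31), and these 2 members passed over the list alone. Pericytes wrap capillaries and are known to multiply when vessels grow. The smallest p values were those of AVPR1A (0.76, SE 0.17) and FABP5 (0.60, SE 0.14) among positive differences, and of MTSS1 (−0.50, SE 0.11) and ADAMTS14 (−1.43, SE 0.39) among negative ones, each at an adjusted p of 1. COL4A1 stood at 0.71 log2 (SE 0.32) and CLDN5 at 0.54 (SE 0.16).

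For 16 lists the arms differed with a preset correlation, 13 higher and 3 lower in BFRT, and for none with an estimated correlation. Without the blood-rich participant 17 lists differed, 8 higher and 9 lower in BFRT, and 8 of the 16 were among them. The pericyte list had adjusted p = 0.472 with an estimated correlation, and its exact permutation p over participants was 0.0329 (0.99 adjusted). Endothelial genes differed by 0.28 log2, complexes II to V by 0.24, complex I by 0.22 and basement membrane by 0.25, each with an adjusted p of 0.911 or 0.912 with an estimated correlation. The same holds for the fatty acid oxidation (0.23 log2), mitochondrial ribosome (0.16), mitochondrial DNA (0.23), angiogenesis (0.19), tricarboxylic acid cycle (0.18), satellite cell (0.18), slow fibre (0.26) and adipocyte (0.32) lists. It also holds for the lists that were lower in BFRT: immediate early (−0.42 log2), inflammatory (−0.33) and fibro-adipogenic progenitor genes (−0.27). Many of these gaps rest on 1 BFRT participant. With the blood-rich participant left out, complex I differed by 0.0145 log2, complexes II to V by 0.041, fatty acid oxidation by 0.057, mitochondrial DNA by 0.0986, mitochondrial ribosome by 0.0144, tricarboxylic acid cycle by −0.03, slow fibre by −0.04, satellite cell by −0.02, inflammatory by −0.07 and immediate early genes by −0.27. Endothelial genes then differed by 0.22 log2, basement membrane genes by 0.24 and angiogenesis genes by 0.12. For ribosome biogenesis, muscle growth, tendon, insulin signalling and neuromuscular junction genes the median, mean and test do not share a sign, and these lists did not pass. The design recovered 19% of simulated 1.5-fold and 69% of 2-fold differences between arms, so 0 genes leaves room for differences of that size. The simulation held no blood-rich pair and changed no low-count genes, so recovery in the real data may be lower. At an unadjusted p below 0.05 the real difference had 444 genes, where 5% of the tested genes is 854.3. Of 60 splits of people between the arms 34 had as many as 444, so this count is usual for random splits. Without the blood-rich participant it was 908.

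**Figure D3:**
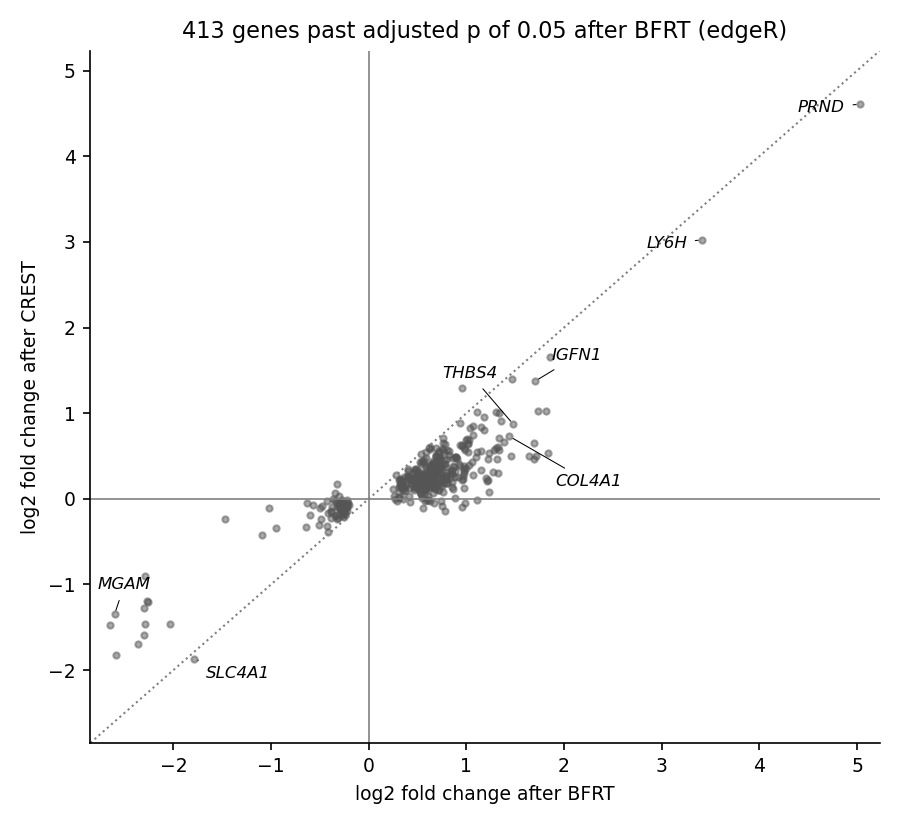
Log2 fold change in BFRT (horizontal axis) against log2 fold change in CREST (vertical axis) for the 413 genes that passed in BFRT. The dotted line marks equal change, and some genes are named, of which PRND and LY6H lie near 0 CPM Before, so that their folds depend on the prior count.

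Averaged over the arms, 644 genes passed, 468 higher and 176 lower, with a median rise of 1.40-fold and 3141 genes at an unadjusted p below 0.05. THBS4 rose by 1.18 log2 (SE 0.15, n = 17, adjusted p = 0.00165) and COL3A1 by 1.14 (SE 0.16, n = 17, adjusted p = 0.00233), each in 17 of 17 people. MYH1, the fastest myosin of human limb muscle, fell by 1.95 log2 (SE 0.49, n = 17, adjusted p = 0.0325), in 14 of 17. Loss of this myosin is known to follow many forms of training. With the blood-rich participant left out 2545 genes passed (1360 higher and 1185 lower). With hemoglobin as a covariate 0 passed (edgeR, 1562 at an unadjusted p below 0.05), with both changes 26, and leaving out 1 CREST participant gave 268.

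The largest rises were those of IGFN1 (1.54 log2, SE 0.28), MXRA5 (1.43, SE 0.21), NMRK2 (1.41, SE 0.33), THY1 (1.38, SE 0.26), SLC26A9 (1.38, SE 0.34) and KIT (1.23, SE 0.23). NMRK2, a nicotinamide riboside kinase gene of muscle, is ENSG00000077009.14 (chromosome 19, 3933069 to 3942416). In the blood-rich participant NMRK2 changed by 6.195 log2 and SLC26A9 by 4.74, the next highest in the arm being 2.73 and 2.13. The largest falls were those of MMP9 (−2.14, SE 0.47), FFAR2 (−2.03, SE 0.37), MGAM (−1.98, SE 0.41), MYH1, FCGR3B (−1.94, SE 0.39) and AQP9 (−1.91, SE 0.42). MMP9, FFAR2, FCGR3B and AQP9 are known neutrophil genes, and hemoglobin fell in 16 of the 17 people. MYH1 went from 10908 ± 6445 to 4780 ± 3532 CPM in BFRT and from 4376 ± 3419 to 1470 ± 2188 in CREST. MYH1 and MYH2 are close paralogs, so their split is less certain than their sum.

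Over both arms 21 of 34 extracellular matrix genes rose over all genes and 26 over the list alone, with a median of 0.48 log2 (1.40-fold), adjusted p = 0.0593 with an estimated correlation and a permutation p = 0.00052 over 17 people. BGN rose by 1.03 log2 and COL5A1 by 0.60 (SE 0.09). Basement membrane genes had a median of 0.46 log2 with 10 of 17 rising (adjusted p = 0.0593 with an estimated correlation), among them LAMB1 (0.85, SE 0.11), COL4A1 (1.09, SE 0.16) and COL4A2 (0.95). Endothelial genes had a median of 0.41 log2 with 10 of 22 rising (adjusted p = 0.0593 with an estimated correlation), ERG (0.56, SE 0.08) and CLDN5 (0.46) among them. Angiogenesis genes had a median of 0.34 log2 with 14 of 32 rising (adjusted p = 0.0714 with an estimated correlation), NRP2 (0.91, SE 0.14), APLNR (0.57) and ESM1 (1.76, SE 0.37) among them. Pericyte genes had a median of 0.36 log2 with 2 of 17 rising, KCNJ8 and PDGFRB (0.42), and adjusted p = 0.31 with an estimated correlation.

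Fibro-adipogenic progenitor genes had a median of 0.23 log2 over both arms with 5 of 21 rising (adjusted p = 0.396 with an estimated correlation), and tendon genes 0.26 with 4 of 10 rising (adjusted p = 0.0593 with an estimated correlation). Matrix protease genes had a median of 0.19 log2 with MMP2 (0.54) and MMP14 (0.51) among the members that rose, and 1 falling, MMP9 (adjusted p = 0.396 with an estimated correlation). Myokine genes had a median of 0.27 log2 with 2 rising (adjusted p = 0.396 with an estimated correlation), and satellite cell genes 0.13 with 3 rising (adjusted p = 0.672 with an estimated correlation). Adipocyte genes had a median of −0.16 log2 (adjusted p = 0.622 with an estimated correlation) and cytosolic ribosomal protein genes −0.05 (adjusted p = 0.716 with an estimated correlation). Glycolysis genes had a median of 0.16 log2 (adjusted p = 0.734 with an estimated correlation).

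Complexes II to V of the respiratory chain had a median of 0.27 log2 over both arms with 3 of 41 rising, COX7A2 (0.33, SE 0.05, adjusted p = 0.00286), COX4I1 (0.34) and UQCRH (0.33), and 41 positive (adjusted p = 0.417 with an estimated correlation, permutation p = 0.00038). Complex I had a median of 0.22 log2 with 37 of 37 positive and 1, NDUFB1 (0.25), rising (adjusted p = 0.585 with an estimated correlation). Mitochondrial DNA genes had a median of 0.21 log2 with 0 passing (adjusted p = 0.428 with an estimated correlation). Tricarboxylic acid cycle genes had 0.18 (adjusted p = 0.63 with an estimated correlation), fatty acid oxidation genes 0.15 with DECR1 rising (adjusted p = 0.622 with an estimated correlation) and mitochondrial ribosome genes 0.12 with MRPS5 rising (adjusted p = 0.792 with an estimated correlation). Leaving out the blood-rich participant lowered the medians and raised the counts: 0.18 log2 with 30 of 41 rising for complexes II to V, 0.12 with 18 of 37 for complex I, 0.13 with 4 of 13 for mitochondrial DNA and 0.07 with 6 of 19 for the tricarboxylic acid cycle. With all participants and hemoglobin as a covariate the medians were 0.0251 log2 for complexes II to V and below 0 for complex I (−0.02), the tricarboxylic acid cycle (−0.08), fatty acid oxidation (−0.02) and the mitochondrial ribosome (−0.07). With that covariate and without the blood-rich participant they were 0.10 log2 for complexes II to V, 0.0702 for complex I, 0.0179 for the tricarboxylic acid cycle and 0.0647 for fatty acid oxidation.

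Red blood cell genes had a median of −1.34 log2 over both arms with 5 of 7 falling, SLC4A1 (−1.83, SE 0.30), ALAS2 (−1.75, SE 0.30) and HBB (−1.33) among them (adjusted p = 0.0593 with an estimated correlation). Lymphocyte genes had a median of −0.79 log2 with 0 passing (adjusted p = 0.428 with an estimated correlation). Ribosome biogenesis genes had a median of −0.10 log2 with 2 of 32 falling, NOP58 (−0.20, SE 0.04) and DKC1 (−0.19), and adjusted p = 0.0714 with an estimated correlation. In lists that did not pass, SCN7A (0.54 log2) of Schwann cells and the cell cycle genes MKI67 (2.07) and TOP2A (1.67) rose, and S100A8, S100A9 and the fast fibre gene ACTN3 (−0.87) fell. For immediate early, clock and insulin signalling genes the median, mean and test do not share a sign.

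Before training, the arms did not differ in any gene at an adjusted p below 0.05 with edgeR (0 of 16136 genes, smallest adjusted p 0.408). At an unadjusted p below 0.05 there were 1478 genes, where 5% of those tested is 806.8, and 1128 without the blood-rich participant. The 0 therefore does not show that the arms were alike. DESeq2 called 9 genes (6 higher and 3 lower) and voom called 0. The smallest p values were those of IGSF9B (0.79 log2, BFRT minus CREST) and GINS1 (0.99) among positive differences and of TEAD2 (−0.81) and CRY1 (−0.40) among negative ones. MYH1 stood at 1.32 log2 (adjusted p = 0.539), from 10908 ± 6445 CPM in BFRT against 4376 ± 3419 in CREST. Fast fibre content is known to differ widely between people, and the TEAD2 estimate includes the blood-rich library.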

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

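The tests of single participants and of the difference between arms were planned, and the tests of explanations for the patterns, those on 8 or 16 participants and the relations to hemoglobin included, were chosen after the result was seen.

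In 202 groups of values, 47 had 1 participant standing far from the others, where chance gives about 5%, and 38 of the 47 were the same BFRT participant. In that person's Before biopsy hemoglobin made up 12.29% of counts (next 0.438%) and in the After biopsy 0.4754% (next 0.104%). Muscle genes changed far more there than in any other BFRT participant, given as mean log2 change with the next value in brackets. For metabolic lists this was complex I 2.09 (0.30), complexes II to V 2.125 (0.37), mitochondrial DNA 1.357 (0.31), tricarboxylic acid cycle 2.305 (0.22), fatty acid oxidation 1.854 (0.42), mitochondrial biogenesis 1.156 (0.14), mitochondrial ribosome 1.512 (0.13), glycolysis 1.954 (0.07) and insulin signalling 0.5456 (0.09). For fibre and muscle lists it was slow fibre 3.581 (0.77), fast fibre 2.005 (0.21), satellite cell 1.952 (0.23), developmental muscle 1.888 (0.60), neuromuscular junction 1.545 (0.31), muscle growth 1.026 (0.11), proteasome 0.8902 (−0.02), heat shock 1.618 (0.05), clock 1.211 (0.14) and calcium handling 2.118 (−0.07).

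Immune lists went the other way in the same BFRT participant: inflammatory −1.714 (−0.41), interferon −2.221 (0.15), macrophage −3.451 (−0.87) and lymphocyte genes −4.814 (−1.61). Among single genes the participant stood apart for THBS4 3.413 (1.93), NMRK2 6.195 (2.73), SLC26A9 4.737 (2.13), TEAD2 1.741 (0.73), PPARGC1A 3.27 (0.72), VEGFA 3.133 (0.78), SLC2A4 3.117 (0.32), MYH2 3.324 (1.19), MYH7 4.449 (0.68), CS 2.278 (0.22), FBXO32 2.447 (0.74), TRIM63 2.58 (0.72) and PECAM1 −1.426 (0.08).

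Other participants stood apart in 9 groups. In BFRT these were lipid droplet genes at −1.052 (next −0.33), PRND at 0.5187 (next 2.51) and a mitochondrial DNA share of 16.57% After (next 20.8%). In CREST they were mitochondrial ribosome genes at −0.1432 (−0.01), ribosome biogenesis at −0.2418 (−0.13), adipocyte genes at −3.815 (−0.44), lipid droplet genes at −1.432 (−0.21), an After total of 51.06 M counts (46.3) and a share of the top 10 genes of 23.44% After (28.7%).

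For 16 lists the change differed between BFRT and CREST by camera at the preset correlation, given as BFRT minus CREST in log2. Higher in BFRT were pericyte 0.5054, endothelial 0.2839, complexes II to V 0.237, complex I 0.2172, basement membrane 0.2534, fatty acid oxidation 0.2289, mitochondrial ribosome 0.1565, mitochondrial DNA 0.2337, angiogenesis 0.1897, tricarboxylic acid cycle 0.1805, satellite cell 0.1761, slow fibre 0.2572 and adipocyte genes 0.3227. Lower in BFRT were immediate early −0.4241, inflammatory −0.3316 and fibro-adipogenic progenitor genes −0.2681. Adjusted p for the pericyte list was 2.27e-11 at the preset correlation and 0.472 with an estimated correlation, and no list passed over participants. Many of these values rest on the blood-rich participant: without that person 8 lists were higher and 9 lower in BFRT, complex I differed by 0.0145, complexes II to V by 0.041, fatty acid oxidation by 0.057 and satellite cell genes by −0.02.

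The lists of matrix, basement membrane and endothelial genes moved up after training, with 21 of 34, 10 of 17 and 10 of 22 members rising over both arms (adjusted p = 0.0593 for each list with an estimated correlation). The blood-rich library as the cause is argued against by the other 8 BFRT participants, in whom the mean change was 0.54 log2 (SD 0.29, exact p = 0.007812, against 0.58 with all 9), and less blood After by the change at no change in hemoglobin, 0.39 log2 (SE 0.12, n = 16, permutation p = 0.01855, against 0.45). A smaller share of fibre RNA would raise other cell types alike. Adipocyte genes stayed 0.86 log2 below (SD 1.17, 15 of 17 people, permutation p = 0.00119), but that is 1 cell type. Schwann cell genes changed by a mean of 0.31 log2 in BFRT and 0.16 in CREST, and macrophage genes by −0.36 and −0.14. The macrophage mean in BFRT includes −3.45 in the blood-rich participant, and the list rose in 5 of 9 BFRT and 4 of 8 CREST people. It also holds the neutrophil genes S100A8 and S100A9, so it does not show a fall of a resident cell type. Other cell types thus give no clear direction, and the adipocyte test does not decide this explanation. Across 17 people the change of these lists and that of hemoglobin had r = −0.330 (permutation p = 0.196) and rho = −0.294. More vessel and connective tissue cells in the biopsy, a smaller share of fibre RNA, higher expression per cell and a processing batch that followed time stay open. Any of them may be the source.

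The lists of nuclear respiratory chain genes moved up after BFRT at the preset correlation, with adjusted p = 0.487 and 0.531 with an estimated correlation, and 2 of 41 and 1 of 37 members rose. The mean change was 0.37 log2 with all 9 participants and 0.15 without the blood-rich one (SD 0.11, n = 8, exact p = 0.01562; each list alone adjusted p = 0.056), which argues against that library as the whole cause. GC content and gene length took the median from 0.36 to 0.3188 log2, and at no change in hemoglobin the mean of the other 8 was 0.12 (SE 0.04, exact permutation p = 0.03906). Over 17 people the lists moved against hemoglobin (r = −0.634, permutation p = 0.00132, adjusted over 3 relations 0.00198; rho = −0.507, permutation p = 0.0399, adjusted 0.0598; r = −0.527 without the 2 farthest people). A part of the rise may therefore follow the blood in the biopsy, and the remainder could be a response of muscle fibres or a processing batch that followed time.

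In BFRT 413 genes passed and in CREST 0 with edgeR. The extra BFRT participant is argued against by leaving out each in turn, where at least 109 genes passed in BFRT against at most 8 in CREST. A larger spread in CREST is argued against by the median SD of 0.2709 there against 0.5327 in BFRT (0.3027 without the blood-rich participant). Both arms were tested in 1 fit that shares the spread, so the SD of CREST alone does not set its test. With each arm fitted alone, 42 genes passed in BFRT and 0 in CREST. At an unadjusted p below 0.05 there were then 1735 in BFRT and 2266 in CREST. Without the blood-rich participant 1595 passed in BFRT and 1 in CREST. A smaller change of the same genes in CREST cannot be told apart from an equal one: over the 644 genes of both arms it was 0.65 log2 in BFRT and 0.43 in CREST (exact permutation p of arms 0.09362).

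Of 60 splits of time within pairs, the real one alone gave 413 genes in BFRT (highest other 190) and 644 for the mean (highest other 383). Chance is therefore unlikely for these, though 60 splits are too few to exclude it. The split with 190 swapped Before and After in 8 of 9 BFRT and 6 of 8 CREST participants, so it is close to the mirror of the real one. Every split matches a real count of 0, so the splits decide nothing for CREST (60 of 60, highest other 0), the difference between arms (60 of 60, highest other 0) or the arms before training (60 of 60, highest other 1). At an unadjusted p below 0.05 the difference had 444 genes, and 34 of the 60 splits had as many (highest other 1168), so chance cannot be excluded for it. That number was 908 without the blood-rich participant, which was not set against splits.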

How the results depend on the processing

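Fits without the blood-rich participant, with hemoglobin as a covariate, with GC content and length and on participant means were chosen after the data were seen, as were, for gene lists, both filter settings and the surrogate variable; the other settings were chosen beforehand. Up to 714 values of named genes were compared per setting, of which 152 had passed in the report. A value counted as reversed only if it passed in either fit and changed sign, and 0 did. Sign changes of values that passed in neither fit were not counted. RLE normalization left 710 the same, DESeq2 628 and voom 649, while hemoglobin as a covariate left 262 the same, with 152 losing their call and 300 moved. Except where a cause is given, the cause was not tested.

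Genes passing in BFRT, 413 in the report, numbered 1050 with DESeq2, 205 with no filter, 1486 with 1 surrogate variable and 42 with only that arm fitted. They numbered 909 with no participant block, 281 higher and 628 lower, and 285 of the 413 were shared. The block changed the BFRT count by over 1.5 times and left CREST at 0 and the difference at 0. Without it 40 results of named genes lost their call and 28 gained one. Without the blood-rich participant 1595 passed, with GC content and length in addition 1874, and with hemoglobin in addition 167. With all participants and hemoglobin as a covariate 0 passed with edgeR in BFRT, CREST, their difference and their mean (1358 in BFRT at an unadjusted p below 0.05). COL4A1 stood at 1.23 log2 with that covariate against 1.44 (SE 0.22). In CREST, 0 in the report, 32 passed with DESeq2, 1 with 1 surrogate variable, 1 without the blood-rich participant and 8 with GC content and length in addition. For the mean, 644 in the report, 1360 passed with DESeq2, 319 with no filter, 2495 with 1 surrogate variable, 2545 without the blood-rich participant, 2997 with GC content and length in addition, 0 with hemoglobin as a covariate and 26 with both. Before training DESeq2 called 9. The difference between arms stayed at 0 in all settings run.

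Of the lists, 24 passed in BFRT, 21 in CREST, 16 for the difference and 22 for the mean. With an estimated correlation these were 0, 0, 0 and 0, with fry 9, 0, 0 and 11, and over participants 9, 0, 0 and 14. The smallest p that exact sign flips can give is higher in CREST (0.00781) than in BFRT (0.00391), so the BFRT and CREST counts over participants are not directly comparable. With 8 BFRT participants, the blood-rich one left out, 9 lists passed over participants. With no participant block 162 list results stayed the same, 2 lost and 8 gained their call, and with RLE 170 stayed the same.

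Leaving out each participant gave 109 to 1595 genes in BFRT, 0 to 8 in CREST and 268 to 2545 for the mean. In BFRT the count moved by over 1.5 times without 1 BFRT participant in 6 cases: 1595 without the blood-rich one and 222, 202, 185, 140 and 109 without another. For the mean it was 2545 without the blood-rich participant, 425 and 411 without another BFRT participant and 283, 373, 268 and 389 without 1 CREST participant. In CREST 1 gene passed without the blood-rich participant, 1 without another BFRT participant and 8 without 1 CREST participant. List medians crossed 0 or the direction against other genes turned for glycolysis (−0.02121 to 0.2604), slow fibre (−0.07872 to 0.3266) and muscle growth (−0.07888 to 0.08183) in BFRT. For the difference this held for mitochondrial ribosome (0.01437 to 0.2072), tricarboxylic acid cycle (−0.02768 to 0.2489), slow fibre (−0.03972 to 0.3787), proteasome (−0.04206 to 0.08748), glycolysis (−0.1199 to 0.122), fast fibre (−0.1018 to 0.21), calcium handling (−0.1389 to 0.1454), lymphocyte (−0.3968 to 0.3795) and neuromuscular junction genes (−0.1803 to −0.024). For each list 1 end of the range is the fit without the blood-rich participant.

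Without that participant the medians in BFRT were −0.02121 for glycolysis, −0.07872 for slow fibre and −0.07888 for muscle growth. For the difference they were 0.01437 for mitochondrial ribosome, −0.02768 for tricarboxylic acid cycle, −0.03972 for slow fibre, −0.04206 for proteasome, −0.1199 for glycolysis, −0.1018 for fast fibre, −0.1389 for calcium handling, 0.3795 for lymphocyte and −0.1803 for neuromuscular junction genes. The direction is set against all other genes, so a reversed list can keep the sign of its median.

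With hemoglobin as a covariate the lists that reversed in BFRT were mitochondrial ribosome 0.01102, lymphocyte 0.2691, satellite cell −0.06624 and glycolysis −0.0398. In CREST they were lymphocyte 0.2594, complexes II to V −0.07629, complex I −0.1247, mitochondrial DNA −0.03402, tricarboxylic acid cycle −0.1217, glycolysis −0.1008, fatty acid oxidation −0.1235, satellite cell −0.2051, mitochondrial ribosome −0.1457 and mitochondrial biogenesis −0.1025. For the mean they were complex I −0.02211, lymphocyte 0.2397, tricarboxylic acid cycle −0.07911, fatty acid oxidation −0.01954, mitochondrial ribosome −0.07045, glycolysis −0.0722 and satellite cell −0.1374.

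Without the blood-rich participant and with hemoglobin as a covariate the lists that reversed in BFRT were mitochondrial ribosome 0.007689, lymphocyte 0.2597, satellite cell −0.07103 and glycolysis −0.044. For the difference they were tricarboxylic acid cycle −0.02539, slow fibre −0.04766, proteasome −0.04126, glycolysis −0.115, fast fibre −0.09674, calcium handling −0.1486, lymphocyte 0.384 and neuromuscular junction −0.1808. For the mean they were lymphocyte 0.05881, mitochondrial ribosome −0.007042, glycolysis 0.01663 and satellite cell −0.02864.

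Without the blood-rich participant and with GC content and length they were, in BFRT, glycolysis −0.0415, slow fibre −0.1122 and muscle growth −0.06981. For the difference they were complex I −0.008462, mitochondrial ribosome −0.01819, tricarboxylic acid cycle −0.04911, satellite cell −0.001148, slow fibre −0.07203, proteasome −0.04785, glycolysis −0.1272, fast fibre −0.1546, calcium handling −0.1394, heat shock −0.02793, lymphocyte 0.3584 and neuromuscular junction −0.1661. With 1 surrogate variable the lymphocyte difference was 0.2798.

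Matrix, basement membrane and endothelial lists reversed in no setting run, and the lists of complexes II to V and complex I did so in those named above. Library totals were 36.97 M counts or more, and the biological coefficient of variation was 26.3%. It was estimated with the participant block, so it holds the spread of changes within people. The part of the error due to depth was not tested.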

Other observations

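The tests here, on myosin shares, on lists over participants, without the blood-rich participant and on neutrophil genes and hemoglobin, were chosen after the result was seen.

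The split of counts among the 3 adult myosin heavy chains, MYH1, MYH2 and MYH7, changed after training. The MYH1 share went from 20.7 ± 14.5% to 7.29 ± 5.21% in BFRT (8 of 9 fell, exact p = 0.0156) and from 6.20 ± 4.89% to 1.96 ± 2.66% in CREST (7 of 8 fell, exact p = 0.0625), by −9.09 ± 11.7 points in all (15 of 17 fell, permutation p = 0.00133). The MYH2 share went from 34.3 ± 8.08% to 44.2 ± 12.2% in BFRT (8 of 9 rose, exact p = 0.0117), from 31.9 ± 12.4% to 37.3 ± 14.7% in CREST (5 of 8 rose, exact p = 0.148) and by 7.78 ± 9.38 points in all (13 of 17 rose, permutation p = 0.00373). The MYH7 share did not pass (permutation p = 0.681). The fall in the MYH1 share was smaller without the blood-rich participant. It was then −9.72 ± 9.46 points in BFRT (7 of 8 fell, exact p = 0.03125) against −13.41 with all. Over 16 people it was −6.98 ± 8.01 points (14 of 16 fell, permutation p = 0.00229), and the MYH2 share changed by 7.62 ± 9.67 (permutation p = 0.00652). In the blood-rich participant the MYH1 share fell although MYH1 itself rose from 4432 to 6095 CPM. A lower MYH1 share is by its definition fewer counts of IIx myosin relative to IIa and slow myosin, so it names no cause. Reads shared between MYH1 and MYH2 were not tested.

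For ribosome biogenesis genes the list mean was −0.11 log2 (SD 0.11) in BFRT, below 0 in 7 of 9 participants, and −0.10 (SD 0.06) in CREST, below 0 in 8 of 8 (permutation p = 0.00022 over 17 people, adjusted 0.0028; in the single arms adjusted 0.072 and 0.168). Over both arms 2 of 32 members fell, and the list had adjusted p = 0.0714 with an estimated correlation. Proliferation genes had an exact p = 0.00781 over BFRT participants (0.0373 adjusted) and a permutation p = 0.00085 over all, with MKI67 at 2.07 log2 and TOP2A at 1.67, while camera did not pass the list.

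Without the blood-rich participant some BFRT lists passed camera at the preset correlation that had not, and an estimated correlation was not run in that fit. Calcium handling genes stood at a median of −0.23 log2, with 14 of 27 members falling, PPP3CA (−0.39, SE 0.10) and ORAI1 (−0.21, SE 0.06) among them, and 0 of 8 people rising (exact p = 0.00781, adjusted 0.0373). Interferon genes stood at 0.31 log2, with 9 of 27 rising, ISG15 (0.71, SE 0.12), IFI27 (0.68, SE 0.10) and IFITM3 (0.35, SE 0.09) among them, and 8 of 8 people rising (exact p = 0.00781, adjusted 0.0373). Proteasome genes stood at −0.09 log2 with 4 falling and 0 of 8 people rising (exact p = 0.00781), and fast fibre genes at −0.25 with 6 falling, ACTN3 (−1.23, SE 0.30) among them (exact p = 0.0391, adjusted 0.0988, so this list did not pass over participants). MSTN fell by 0.98 log2 (SE 0.28) in that fit. FST fell by 0.91 (SE 0.22), PER2 by 0.41 (SE 0.10) and PECAM1 rose by 0.67 (SE 0.15).

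Hemoglobin fell after training in 16 of 17 people. If the After biopsies held less blood, neutrophil genes should fall too, and CXCR2, CSF3R, S100A8, S100A9 and S100A12 changed by −1.35 log2 (SD 1.32, 15 of 16 people fell, permutation p = 0.00059), beside −1.41 for the red blood cell genes SLC4A1, AHSP and ALAS2. Over 17 people the changes in neutrophil genes and in the hemoglobin share had r = 0.902 (permutation p = 1e-05, the smallest that the resamples can give, adjusted 3e-05) and rho = 0.831 (permutation p = 4e-05), and r = 0.742 without the 2 farthest people. Less blood in the After biopsies is a candidate explanation for the falls of MGAM, FFAR2 and the hemoglobin genes, and fewer circulating neutrophils were not tested.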
